A study of Mus musculus with 2 samples.

How the data were processed

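CTCF binding was measured by chromatin immunoprecipitation and sequencing in kidney tissue of newborn B6NCrl mice (age 0 days after birth). The 2 libraries form 1 group, and the labels number them as biological replicates 1 and 2. The labels give both libraries the same biosample and donor identifiers, so spread between them and p-values that rest on it may be technical. The labels name no sex and no second group, and no comparison between groups was made.

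The authors deposited 5 peak lists in narrowPeak format on the mm10 assembly: 1 list for each library, 1 list made from both libraries pooled, and the conservative and optimal lists thresholded for reproducibility between libraries (irreproducible discovery rate, IDR), per the file headers and the notes beside them. Per those notes every list used 1 other alignment file as a further source. The aligner, the peak caller, the filters and the IDR threshold are not given in the sources used here. In each list the authors' signal value was taken as their caller gave it. Its scale depends on library depth, so it was used only as a rank or percentile within a list. The deposited q-value column is on the −log10 scale and reached 1 highest value in each list that many peaks shared (60069 peaks of the optimal list), so it ranked nothing here. The authors' score column was filled only in the thresholded lists and was not used here. The deposited summit offset gave the position of each peak's summit. The lists hold no read counts, so sequencing depth is unknown, and no value below is scaled for it. Each list matched the checksum given beside it.

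All coordinates are mm10, 1-based. They were combined with the GRCm38.p6 genome sequence, the same assembly, and GENCODE M21 genes; every peak and gene end on chromosomes 1 to 19 and X lay within the chromosome's length. Tests used these 20 chromosomes, which hold 65470 of the 65482 optimal peaks; the other 12 lie on unplaced contigs. Intervals were handled with bedtools 2.31.1 and samtools 1.23.1, and statistics with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. The background for genes was 21755 protein-coding genes with 93145 distinct annotated transcription start sites (TSSs). The upper set of each library's list, with as many peaks as the optimal list, stood for that library on its own. The upper-signal part of the optimal list is the 50% of its peaks with the highest signal.

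The libraries were compared by overlap of at least 1 bp, against 100 random placements of the intervals on their chromosomes, and by Spearman's rho over optimal peaks with 1000 permutations. Summits within 1 kb of a TSS were counted against 1000 random placements outside assembly gaps. A CTCF motif matrix of 19 bp was learned from peaks on odd-numbered chromosomes, starting from the consensus CCASYAGRKGGCR, and scored within 100 bp of summits on even-numbered chromosomes and X, against windows 2 kb away (exact McNemar test); a match passed the score that 1 in 10000 control positions passed. The consensus of that matrix was AGGCCAGAAGAGGGCACCA, and 42.2% of its matches under peaks lay in soft-masked sequence (interspersed and simple repeats). A second matrix was therefore learned with soft-masked bases left out, a choice made after seeing the data; its consensus was TGGCCACCAGGGGGCGCTA. Motif directions at single loci come from this second matrix. Gene lists were tested with Fisher's exact test (two-sided) on promoter peaks, with Benjamini-Hochberg adjustment over 21 lists, and loci by peaks in the span of their genes plus 50 kb on each side against 10000 random windows of the same length (one-sided, adjusted over 32 loci). Medians of signal percentile were compared with 100000 resamples, and motif directions with 1000 permutations of strands within chromosomes. Peaks and genes are not independent replicates, and clustered genes can share a peak, so these p-values describe the lists, not a population of mice. Intervals are 95% Wilson intervals and cover counting error only.

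Lists, loci, tests, alternatives and the rule for naming were fixed before the data were examined, except where the text says otherwise. The text names the 10 highest-signal optimal peaks with their nearest protein-coding gene, the highest-signal peak of 6 fixed loci and of any locus past the threshold, up to 4 members of each list with the highest-signal promoter peak that lay in the upper set of both libraries, and up to 3 members of kidney lists without a promoter peak. Symbols Sororin, Znf143 and Ahsp had no entry in the annotation, and non-coding members of lists were described and not tested. The gene list, motif direction, median difference, rank correlation and motif statistics were tested on simulated data; the locus, promoter placement and library overlap tests were not. Of simulated lists of 60 genes with peaks at 75% of promoters, 99.8% were called, of lists of 22 genes at 60%, 18.5% were called, and of unchanged lists, 0.563% were called. Simulated lists were drawn at random, and their genes had independent peaks with a common background rate. These rates may therefore not hold for clustered genes or for lists that differ in promoter CpG ratio. Alternatives covered the peak set, the library, windows, thresholds, backgrounds and the matrix.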

Results

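CTCF, the zinc-finger protein that marks insulators and loop anchors, was mapped in newborn mouse kidney in 2 libraries of 1 group. The optimal list held 65482 peaks and the conservative list 59444. Each library's own relaxed list and the pooled list held 300000 peaks. Per-library depth is unknown, because the lists hold no counts. Of the conservative intervals, 54860 (92.3%) were also in the optimal list.

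None of the 10 highest-signal sites lay within 1 kb of a TSS (transcription start site) of a protein-coding gene. The highest-signal peak lay on chromosome 8 from 70629658 to 70630155, in a coding exon of Gdf15, a stress-induced growth factor, 2172 bp from a TSS; all positions are mm10. The next peaks by signal lay 9306 bp from Trpv4, a cation channel gene (chromosome 5), and in introns of Fam129b (chromosome 2) and of Pink1, a mitochondrial kinase gene (chromosome 4). Intergenic peaks near Enah, Glrx3, Npvf, Rbm19 and Gtf3c5 and a UTR peak of Ptges2 completed the 10 highest. The peak nearest Npvf was the farthest from a TSS, at 282867 bp. All 10 carried a motif match of the matrix learned outside soft-masked sequence. The match at the Pink1 peak, TTACCACTAGGTGGCGCTA, lay from 138319715 to 138319733 on the forward strand. The match at the Gdf15 peak, CCGCCGGCAGGGGGCGCCG, lay from 70629892 to 70629910 on the reverse strand. The Pink1 peak ranked 2 in replicate 1 and 6 in replicate 2, and the Gdf15 peak ranked 29 and 1.

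The libraries largely listed the same sites. Of the upper peaks of replicate 1, 79.9% overlapped an upper peak of replicate 2, and 86.6% did in the reverse direction. Random placement gave 1.54% on average and 1.63% at most (permutation p = 0.0099, the smallest that 100 placements can give). With the whole relaxed lists the share was 40.8%, and 45.0% in the reverse direction, against 7.67% on average for random placement. Over 63805 optimal peaks matched in both libraries, ranks had a Spearman's rho of 0.911 (permutation p = 0.001, the smallest that 1000 permutations can give). The optimal list was thresholded for reproducibility, so this value describes selected peaks. Of the optimal peaks, 1665 lacked a match in at least 1 library. In the conservative list 128 peaks lacked one, and rho was 0.932 over 59307 matched peaks. In the pooled list, which was not thresholded for reproducibility, rho was 0.901 over as many highest-signal peaks as the optimal list holds (64065 matched). All optimal intervals lie in the pooled list, at a median rank of 32750.5, and both libraries made its ranking. The value of 0.901 is therefore no separate check. Over all pooled peaks rho was 0.848, with 122142 matched in both libraries and 177784 not. Of all optimal peaks, 78.6% overlapped an upper peak of both libraries, from 8.08% in the lowest signal decile to 100% in the highest.

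**Figure D1:**
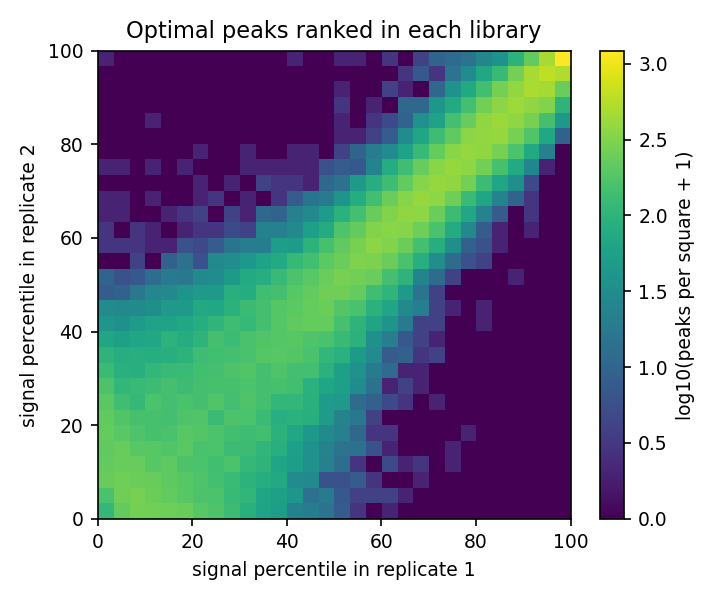
Signal percentile of each matched optimal peak in replicate 1 (horizontal axis) and replicate 2 (vertical axis), as the number of peaks per square plus 1 on a log10 scale. The plotted peaks come from a list thresholded for reproducibility and were matched in both libraries. They have a Spearman's rho of 0.911 over 63805 peaks, lie along the diagonal at high percentiles and spread more at low percentiles. In the columns of replicate 1 from percentiles 10, 13.3 and 16.7, the fullest square was the lowest of replicate 2. Those squares held 271, 251 and 237 peaks against 191, 176 and 190 on the diagonal.

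Promoters held more CTCF peaks than random placement gave. Within 1 kb of a TSS lay 10898 optimal peaks, 16.6% (95% Wilson interval 16.4 to 16.9), against 4.04% for random placement (permutation p = 0.001, two-sided, the smallest that 1000 placements can give). Against the lowest-ranked 50% of the pooled list in place of random positions, the background was 8.50% (permutation p = 0.001). The share was 16.2% in replicate 1 and 17.4% in replicate 2. Introns held 37.4% of summits against 35.5% at random, coding exons 1.78% against 1.04%, and intergenic sequence 41.6% against 57.6%. Over all peaks, promoter peaks had lower signal than distal peaks: their median signal percentile was 42.6 against 51.6, a difference of -8.99 points (permutation p = 1e-05, the smallest that 100000 resamples can give). The difference was -7.96 points in replicate 1 and -9.32 in replicate 2. It turned among peaks with a match of the motif matrix learned outside soft-masked sequence, where the medians were 65.3 for promoter and 59.3 for distal peaks, and was small among the others, at 30.3 and 32.3; these differences were not tested.

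Of 21755 protein-coding genes, 8576 (39.4%) had a promoter peak. The share rose from 5.65% of genes in the lowest decile of promoter CpG ratio to 58.6% in the eighth. Of the 21 gene lists, 5 differed from other genes at an adjusted p under 0.05, 2 above and 3 below. With replicate 2 left out 8 lists passed and with replicate 1 left out 10, with the conservative list 9, and in the upper-signal part of the list 3. Each list's share and adjusted p come from Fisher's exact test.

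Clustered protocadherins, neuronal adhesion genes with stochastic promoter choice, had a promoter peak at 42 of 57 members, or 73.7% against 39.3% of other genes (adjusted p = 1.3e-06, Fisher's exact test). The highest-signal peaks were at Pcdhgc3, Pcdhgb6, Pcdhac1 and Pcdhga12, at signal percentiles of 71.2, 61.4, 60.3 and 60.1. The share was 80.7% in replicate 1 and 57.9% in replicate 2. In the upper-signal part of the optimal list it was 12.3% against 19.8% of other genes, which did not pass the test (adjusted p = 0.470, Fisher's exact test). Ribosomal protein genes had promoter peaks at 50 of 82 members, 61.0% against 39.3% (adjusted p = 0.000501, Fisher's exact test), with Rplp0, Rpl36 and Rpl26 among the highest, at percentiles of 98.4 to 98.8. Against genes of the same promoter CpG ratio the expected share was 54.3% and the difference did not pass the test (adjusted p = 0.644, permutation).

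Chemosensory receptor genes had almost no promoter peaks. Olfactory receptors had one at 11 of 1093 members, 1.01% against 41.5% (adjusted p = 4.88e-221, Fisher's exact test), among them Olfr557, Olfr156, Olfr15 and Olfr1499. Vomeronasal receptors had one at 1 of 327 members, Vmn1r20 (0.306%, adjusted p = 3.96e-69, Fisher's exact test). Both stayed below the share expected at their promoter CpG ratio, 10.4% and 9.48% (adjusted p = 0.000105 for each, the smallest that the resamples can give for a pair of lists, permutation). Immune cell genes had promoter peaks at 2 of 22 members (9.09%, adjusted p = 0.0144, Fisher's exact test), with C1qa, a complement gene, among them. The share was 4.55% in each library alone. The difference did not pass the test with promoters of 2500 bp on each side, 22.7% against 49.9% (adjusted p = 0.059, Fisher's exact test), or in the upper-signal part of the list (adjusted p = 0.416, Fisher's exact test). At their promoter CpG ratio 19.9% was expected and the difference did not pass the test (adjusted p = 0.644, permutation).

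No kidney list passed the threshold in the optimal list. Renal stroma genes had promoter peaks at 14 of 23 members (60.9%, adjusted p = 0.11, Fisher's exact test), with peaks at Col1a1, Gli1, Itga8 and Aldh1a2 between percentiles 86.2 and 97.4. Pdgfrb, Meis1 and Sfrp1 had none. Each library alone gave 65.2%, and the adjusted p was then 0.0435 for replicate 1 and 0.0488 for replicate 2 (Fisher's exact test). Over all alternatives the adjusted p ran from 0.0273, with promoters of 2500 bp on each side, to 0.416 in the upper-signal part of the list (Fisher's exact test). At their promoter CpG ratio 37.4% was expected (adjusted p = 0.0819, permutation). Proximal tubule genes had them at 4 of 25 members (16%, adjusted p = 0.0608, Fisher's exact test). They passed with the conservative list (adjusted p = 0.0293, Fisher's exact test) and with replicate 1 left out (adjusted p = 0.0488, Fisher's exact test), and the adjusted p reached 0.470 in the upper-signal part of the list (Fisher's exact test). At their promoter CpG ratio 30.1% was expected and the difference did not pass the test (adjusted p = 0.343, permutation). Slc7a7, a cationic amino acid exchanger subunit, and Slc13a3, a dicarboxylate transporter, had one in the upper set of both libraries, and Cubn, Slc34a1 and Slc34a3 had none. Nephron progenitor genes had promoter peaks at 10 of 22 members (45.5%), with Itga8, Jag1 and Osr1 among the highest, and Cited1, Eya1 and Sall1 without one. Podocyte genes had them at 11 of 22 (50%), with Vegfa, Kirrel and Magi2 among the highest, and Nphs1, Podxl and Synpo without one. Loop of Henle and distal tubule genes had them at 10 of 25 (40%), with Wnk1, Irx1 and Pvalb among the highest, and Umod, Slc12a1 and Slc12a3 without one. Ureteric bud and collecting duct genes also had them at 10 of 25, with Scnn1g, Wnt7b, Elf5 and Wnt11 highest, and Ret, Wnt9b and Aqp2 without one. The smallest adjusted p of these last 4 lists was 0.473 (Fisher's exact test).

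Among the other lists, imprinted genes had promoter peaks at 21 of 39 members (53.8%, adjusted p = 0.126, Fisher's exact test), with Ppp1r9a, Commd1, Grb10 and Mest highest. Of imprinted non-coding genes, Airn and Meg3 had a peak within 1 kb of a TSS, and H19, Kcnq1ot1, Rian and Mirg did not. Cohesin and CTCF-associated genes had promoter peaks at 14 of 24 members (58.3%, adjusted p = 0.12, Fisher's exact test), led by Stag1, Esco1, Pds5b and Chd8. Clustered Hox genes had them at 12 of 39 (30.8%, adjusted p = 0.428, Fisher's exact test), and 51.4% was expected at their promoter CpG ratio (adjusted p = 0.046, permutation). The highest were at Hoxa7, Hoxb5, Hoxc10 and Hoxc5; Hoxc10 and Hoxc5 share a peak. Zfp genes had them at 164 of 365 (44.9%), led by Zfp398, Zfp638, Zfp786 and Zfp113. Solute carriers had them at 152 of 361 (42.1%), led by Slc39a13, Slc36a1, Slc2a4 and Slc6a19. Among lists of other cell types, erythroid genes had 2 of 17 (with Epor), hepatocyte genes 3 of 21 (with Apob and Afp), endothelial genes 6 of 20 (with Vwf, Ehd3, Egfl7 and Esam), and neuronal genes 5 of 21 (with Rbfox3, Gap43, Elavl4 and Gad1). Muscle genes had 5 of 21, with Ckm, Ttn, Tnnt3 and Myod1 highest. By Fisher's exact test on the optimal list, none of the lists in this paragraph passed the threshold, and the smallest adjusted p among them was 0.0608. Some passed under alternatives. Hepatocyte genes passed with either library left out, the conservative list, peaks near a higher-signal peak left out, or gene 5' ends only (adjusted p = 0.0201 to 0.0488, Fisher's exact test), but not at matched promoter CpG ratio (adjusted p = 0.941, permutation). Cohesin genes passed with the conservative list (adjusted p = 0.00553, Fisher's exact test) and with replicate 1 left out (adjusted p = 0.0488, Fisher's exact test), and erythroid genes with replicate 1 left out (adjusted p = 0.0488, Fisher's exact test). Solute carriers passed with the conservative list (adjusted p = 0.0413, Fisher's exact test) and with replicate 2 left out (adjusted p = 0.0315, Fisher's exact test), and Zfp genes with gene 5' ends only (adjusted p = 0.0154, Fisher's exact test). At matched promoter CpG ratio none of these passed: the adjusted p was 0.959 for cohesin genes, 0.685 for erythroid genes, 1 for solute carriers and 0.959 for Zfp genes (permutation).

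**Figure D2:**
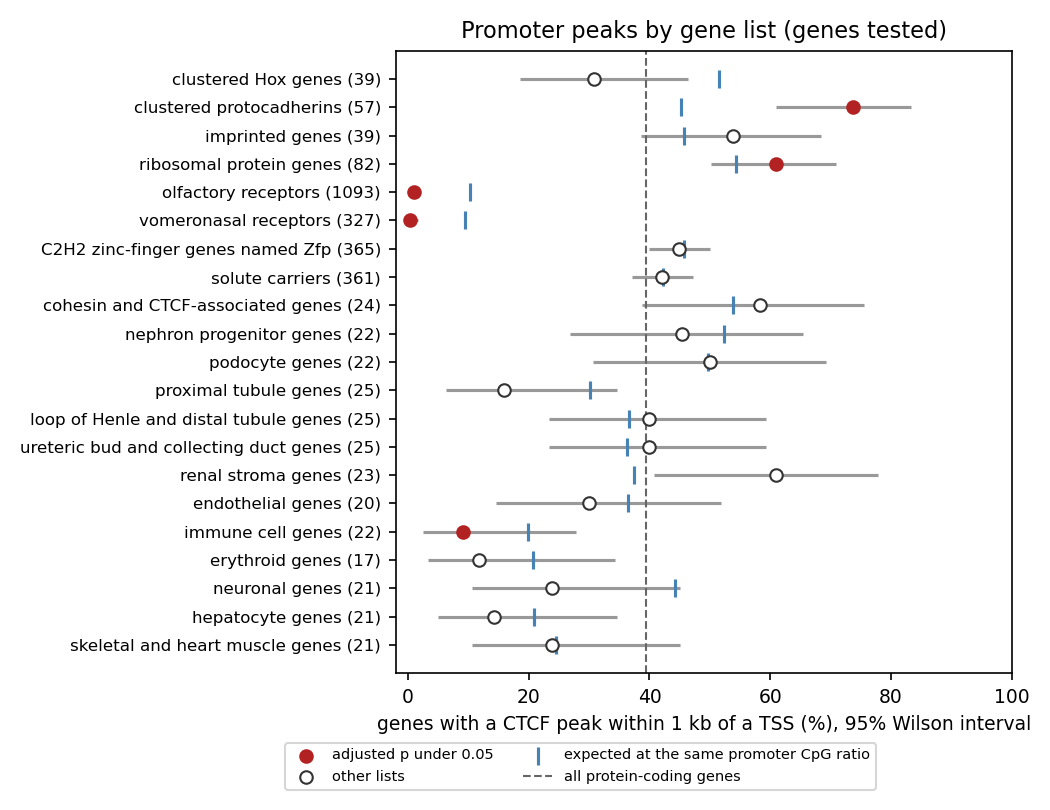
Share of each list's genes with a CTCF peak within 1 kb of a TSS (circles, 95% Wilson interval), filled where the adjusted p was under 0.05, with the share expected at the same promoter CpG ratio (ticks) and the share of all protein-coding genes (dashed line, 39.4%). Protocadherins lie highest at 73.7% and vomeronasal receptors lowest at 0.306%.

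Firre, a non-coding gene on X, had more peaks than random windows. In its span plus 50 kb on each side lay 32 peaks against a mean of 4.58 in random windows (adjusted p = 0.0128, permutation, one-sided). The count was 33 in replicate 1 and 36 in replicate 2, and against windows centred on TSSs the adjusted p was 0.0192 (permutation). Between the ends of Firre (X, 50555744 to 50635321) lay 27 peaks, of which 15 had a motif match, 4 forward and 11 reverse. Their signal percentiles ran from 15.7 to 72.6. The highest-signal peak of the window, at 50658029, lay outside the gene at percentile 90.7 and had no motif match.

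**Figure D3:**
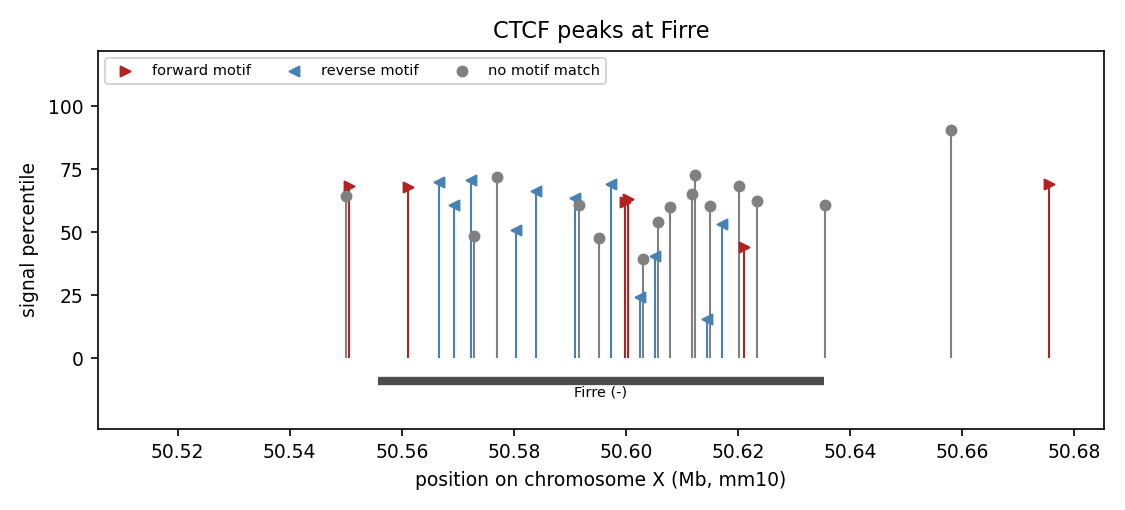
CTCF peaks in the Firre window on chromosome X (horizontal axis, Mb) with their signal percentile (vertical axis), coloured by motif direction; the bar marks the gene. Between the ends of the gene, 11 of 15 motif matches point in reverse.

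No other locus of the 32 passed the threshold. HoxB had 28 peaks against 6.89 (adjusted p = 0.149, permutation), and the alpha-globin cluster had 14 against 3.06 (adjusted p = 0.149, permutation). Igf2-H19, an imprinted pair, had 17 peaks against 4.88 (adjusted p = 0.279, permutation), with its highest peak at 142672321 on chromosome 7, at percentile 92.9. HoxA and HoxD had 13 peaks each, with their highest peaks 46 bp from a Hoxa7 TSS (percentile 97.8) and in an intron at Hoxd3 and Hoxd4 (percentile 98.0). The Tsix-Xist-Ftx window had 12 peaks, with the highest at 103484236 on X. Six2-Six3, which holds the nephron progenitor regulator Six2, had 13 peaks, and its highest lay 12798 bp from a Six3 TSS. Wt1, which encodes a regulator of kidney development, had 5, and its highest lay 25649 bp from a Wt1 TSS.

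Motif matches lay under many summits and close to them. With the matrix learned from all sequence, 13867 of 30548 peaks on even-numbered chromosomes and X had a match, 45.4% (95% Wilson interval 44.8 to 46.0) against 1.81% of control windows. Of the pairs that differed, 13577 had the match only at the peak and 262 only in the control, and the base-10 logarithm of the exact McNemar p was -3603. The share was 44.7% in replicate 1 and 43.9% in replicate 2. At the score that 1 in 100000 control positions passed, it was 9.40%. That score lay above the median of soft-masked matches (21.9) and of other matches (17.7), so this share may rest largely on soft-masked matches. Over all chromosomes this matrix matched 82.7% of peaks with a soft-masked summit and 35.1% of other peaks. With the matrix and threshold from outside soft-masked sequence, the share on even-numbered chromosomes and X was 67.7% against 2.70% of control windows. Over all chromosomes, those it was learned from included, 38.8% of promoter peaks and 73.4% of distal peaks had a match of that matrix. Over the same chromosomes its share rose from 36.8% in the lowest signal decile to 91.9% in the highest.

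Motif score and signal were related in opposite directions by the 2 matrices. Over 29868 peaks with a match of the matrix learned from all sequence, Spearman's rho was -0.244 (permutation p = 0.001). Over 44296 peaks with a match of the other matrix it was 0.299 (permutation p = 0.001). Both are across peaks. The negative value was not kept within classes of matches of the matrix learned from all sequence. There rho was 0.202 outside soft-masked sequence and 0.0863 within it.

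**Figure D4:**
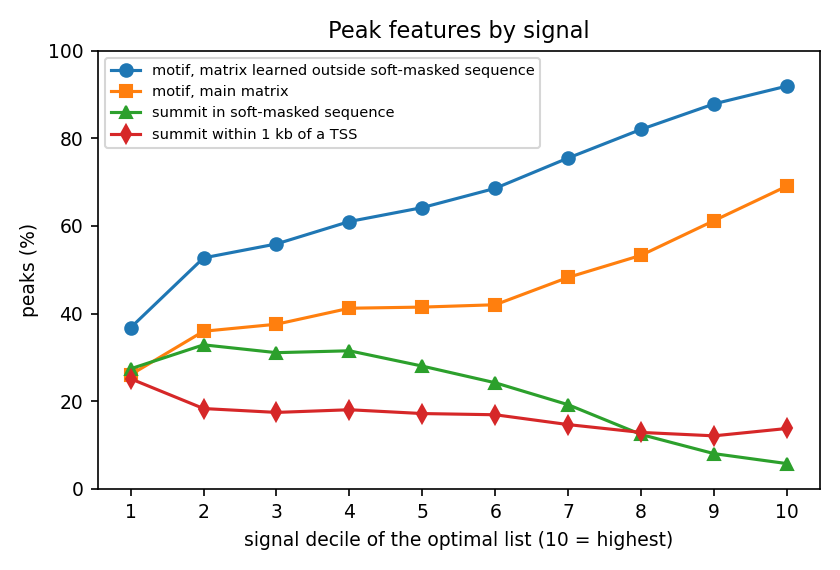
Share of optimal peaks (vertical axis, %) in each signal decile (horizontal axis, 10 the highest) with a motif match of each matrix, with the summit in soft-masked sequence and with the summit within 1 kb of a TSS. Matches rise with signal to 91.9% and 69.1%, and soft-masked summits fall to 5.76%.

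Among neighbouring motifs 10 to 500 kb apart, convergent pairs, which point at each other, were slightly more frequent than with permuted strands. Along a chromosome convergent and divergent pairs alternate, so over all adjacent pairs their numbers are nearly equal. A difference between them within a distance range therefore describes how spacing varies with motif direction. Matches here are those of the matrix learned from all sequence, unless stated otherwise. Of 21981 adjacent pairs 10 to 500 kb apart, 25.5% were convergent against 25% with permuted strands (permutation p = 0.019), 50.7% were in tandem against 50% (permutation p = 0.042), and 23.9% were divergent against 25% (permutation p = 0.001). The tandem share did not pass the test with the conservative list (50.1%, permutation p = 0.847), with replicate 1 left out (50.4%, permutation p = 0.257) or with peaks near a higher-signal peak left out (permutation p = 0.0549). In the upper-signal part of the list 26.9% were convergent (permutation p = 0.001), 48.1% were in tandem, below 50% (permutation p = 0.001), and the divergent share did not differ from chance by the test (permutation p = 0.970). With the matrix and threshold from outside soft-masked sequence, 25.5% of 30167 pairs were convergent (permutation p = 0.00599). Of those pairs, 51.6% were in tandem and 22.9% were divergent (permutation p = 0.001 for each). For the matrix learned from all sequence, the convergent share lay below its permuted mean under other distances and a stricter score. At the score that 1 in 100000 control positions passed, the convergent share was 24.2% (permutation p = 0.068). That score lay above the median of soft-masked matches (21.9) and of other matches (17.7), and closer to the former. The stricter setting may therefore rest largely on soft-masked matches. From 10 to 200 kb the convergent share was 24.8% and did not pass the test (permutation p = 0.372). At any distance over 1 kb it was 24.3%, below its permuted mean (permutation p = 0.001). With almost no distance limit, that share largely mirrors the tandem share. It therefore does not show a lack of convergent pairs of its own.

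Peaks on X were sparser than on any autosome. X held 1614 optimal peaks, 9.87 per Mb, against 20.4 to 40.8 per Mb on autosomes. The median signal percentile of X peaks was 51.6 against 49.9 for autosomes, a difference of 1.66 points that did not pass the test (permutation p = 0.188). In the upper-signal part of the list, X peaks were lower by a difference of -16.9 points (permutation p = 1e-05).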

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

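The optimal list held 12 peaks on unplaced contigs and the conservative list 9, which the comparisons above left out. They are listed because each count exceeded 3, the limit that a count of 0 allows; no control list was at hand, so the counts show only that such peaks were called. They lay on 7 contigs and ranked from 62 to 64350 in the optimal list, with 5 in its upper-signal part.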

How the results depend on the processing

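Alternatives that used the matrix from outside soft-masked sequence, left out peaks within 500 bp of a higher-signal peak, or ranked the pooled list between libraries, were chosen after seeing the data. The number of peaks, the overlap and rank correlation of libraries, the promoter share, the motif share, the promoter signal difference and the number of loci past the threshold kept their direction and side of the threshold under each alternative run, but the promoter signal difference was turned among peaks with a motif match (medians 65.3 and 59.3). Gene lists past the threshold were 5 in the main setting, 9 with the conservative list, 3 with the upper-signal part of the list, and 8 to 10 with 1 library left out; with other alternatives they were 4 to 7. The protocadherin share was below that of other genes in the upper-signal part (12.3%) and did not pass the test there. For the matrix learned from all sequence, the convergent share turned under its permuted mean in some settings. It was 24.8% up to 200 kb and 24.3% at any distance over 1 kb. At the score that 1 in 100000 control positions passed, it was 24.2%. Of these shares only 24.3% passed the test, and with almost no distance limit it largely mirrors the tandem share. With the matrix from outside soft-masked sequence, the convergent share stayed above its permuted mean, at 25.5%. The correlation of motif score and signal turned to 0.299 with the matrix from outside soft-masked sequence. The X difference was -1.08 points with the conservative list and -16.9 in the upper-signal part, and 0.192 to 1.55 with 1 library left out. Except for the motif correlation, for which tests are given below, the cause was not tested. Single lists and loci gave 370 values on the side of the threshold of the main setting, 17 that newly passed and 4 that no longer passed. Another 1, the protocadherin share in the upper-signal part, turned and no longer passed. Changes of direction among values that passed in neither setting were not counted as turned. Clustered Hox genes, for example, lay below other genes in the main setting but at 51.3% against 49.9% with promoters of 2500 bp on each side. No value without a library exists for the number of peaks, the overlap or the rank correlation, which need both. No paired analysis was possible because the study has 1 group. Unknown depth limits any statement on peaks missing from a list.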

Other observations

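The tests of soft-masked matches, of the upper-signal part, of sex composition, and of soft-masked sequence and signal on X were chosen after the result or a value close to it was seen; those of GC content and gene number were set before. The densest window of 200 kb lay on chromosome 18 and held 37 peaks with 3 protein-coding genes, Ube2d2a, Cxxc5 and Psd2, and 1 peak near a TSS. The next, on chromosome 11, held 35 peaks with 10 genes, among them Csf3, Med24 and Thra. A window on chromosome 7 with Foxa3, Sympk and Six5 held 31 peaks, of which 23 had a motif match. These windows were chosen by their counts. Of soft-masked summits, 88.1% had a match of the second matrix against 61.9% of other summits, and their median signal percentile was 35.9 against 55.4. The threshold for these matches came from control positions outside soft-masked sequence. The background of matches may therefore differ between these classes of summits.

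The negative relation of motif score and signal may come from mixing matches in repeats with other matches, since it was absent within each class. Outside soft-masked sequence rho of the matrix learned from all sequence was 0.202 over 17274 matches, and within soft-masked sequence it was 0.0863 over 12594. Soft-masked matches had a higher median score, 21.9 against 17.7, and a lower median signal percentile, 37.2 against 76.9. Low-signal peaks do not account for it alone, since rho was still -0.0743 in the upper-signal part. No biological explanation was tested, since the design has 1 group.

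Ranks of the same peak differed between libraries by a median of 6.56 percentile points. GC content stays open as a candidate explanation: rho of the rank difference, replicate 1 minus replicate 2, with GC content was 0.0659, between the bounds of 0.05 and 0.1 set before the value was seen. The 1000 peaks ranked most above in replicate 1 had a median GC content of 49.3% with 14.8% near a TSS, and those in replicate 2 had 44.8% with 25.3%. A different sex composition of the libraries is not settled by the tables: the labels give both the same donor, X peaks were shifted against autosomal peaks by -0.953 points (permutation p = 0.0004), and the upper sets held 1648 X peaks in replicate 1 and 1592 in replicate 2. The whole relaxed lists held 6091 and 7608, a ratio of 1.25 outside the autosomal range of 0.941 to 1.06.

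The low density on X was not brought into the autosomal range by scaling to sequence outside repeats or to gene number. With all peaks counted over the length outside soft-masked sequence, X held 18.5 per Mb against 31.8 on the lowest autosome. Peaks in soft-masked sequence stayed in these counts, so a density of peaks outside it was not measured. Per protein-coding gene X held 1.70 against 2.08. Whether lower signal of X peaks may contribute stays open: 1.30% of X peaks lay in the top signal decile against 8.78% on the lowest autosome, but their median percentile was 51.6 against 49.9 on autosomes. The low density was also present in the pooled list, which was not thresholded for reproducibility. There X held 36.6 peaks per Mb against 99.2 to 177 on autosomes. No list held a peak on Y, and mapping filters that could remove such peaks are not given in the sources used here.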
